A study of Homo sapiens with 12 samples.

How the data were processed

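Gene expression and splice junctions were measured by RNA sequencing in 3 cell lines with wild-type or mutant U1, 2 technical replicates per group, 12 libraries in all. Per the labels' protocols, total RNA was extracted with Trizol and stranded libraries were made after ribosomal RNA depletion. Per the submitters' processing notes, STAR 2.5.4b and HTSeq 0.9.1 were used with the builds hg19 and GRCh37. The strand setting of the counting and the annotation release are not given in the sources used here. Groups and replicate numbers were taken from the labels. Nothing states that replicates came from separate cultures, and the series text calls them technical, so p-values within a line measure the spread between technical replicates only.

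The gene file holds raw read counts per gene, as deposited by the authors, for 57820 genes, and 39538 of the IDs had a symbol in the gene name table used here. Lines that name no gene were left out of library sizes and tests. Reads outside features took 17.72% to 24.93% of all entries per library, ambiguous reads 0.9% to 1.06% and reads that did not align uniquely 29.02% to 34.92%. Totals were 29880079 to 39716818 counts per library. The technical replicates of each group differed by more than counting noise, with a mean chi-square per gene of 2.28 to 5.29 at 1 degree of freedom, so none was taken as a library deposited again.

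The junction file holds raw junction counts deposited by the authors in 6 columns, 1 per line and status, for 170723 junctions, with 15537369 to 17917160 reads per column. The columns carry no replicate number and hold 23.6% to 25.3% as many reads as the summed gene counts of both replicates. They were taken as pooled, so tests planned on 12 junction libraries could not be made. Junctions within a line are given by size with no test. How junctions were extracted and filtered is not given in the sources used here.

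Coordinates are as in the junction file, in hg19. The file gives no gene names, and no hg19 annotation was used. Each cluster of junctions was therefore matched by the exact lengths of its introns to genes of GENCODE release 29, which is on another build, and the gene ID was named through the gene name table. No coordinates were converted or taken from that build. At least 3 introns had to match, and at least 2 times as many as for the next best place. Of 38215 clusters, 34571 (90.5%) were matched, against 34 (0.09%) when each was offered a wrong chromosome. Names of junctions therefore rest on this match. "Annotated" means that the intron is in that release. Start and end are the last base of one exon and the first base of the next, since 99% of deep junctions had a length found in the annotation on that reading.

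Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05. Across lines, replicates were summed to 3 mutant and 3 wild-type libraries, with the line as a block. Within lines and for differences between lines, the 12 libraries were fitted as 6 groups. The SE given with a log2 fold change is that of the 3 lines' values. CPM within a line were from summed replicates, with exact binomial 95% intervals for ratios and a floor of 3 counts over the group for a count of 0. Intervals cover counting error only. The floor covers the count of 0 alone and takes the other group's count as exact. A fold given as "at least" is therefore not a 95% bound, and with few counts no change may not be excluded.

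Junction use is the percent of reads among all junctions that share an acceptor, which compares the donors that compete for it. It was tested with edgeR's diffSpliceDGE on junctions of at least 20 reads, in groups of at least 2, with the line as a block. A call needed an adjusted p under 0.05, a mean change of at least 5 points and the same sign in every line. Percentages in single columns carry 95% Wilson intervals.

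Before the data were examined, 36 gene lists were fixed, and 35 had at least 5 tested members. They were tested with limma 3.58.1 camera (correlation 0.01, log2 values with a prior count of 2), and again with an estimated correlation. Under the latter 0 lists passed and 1 had an unadjusted p under 0.05. That version has only the few degrees of freedom left by 3 mutant and 3 wild-type libraries with the line as a block. All 35 lists had an adjusted p of 0.923 to 0.98 under it. Among them were integrated stress response, B cell identity and p53 targets, with estimated correlations of -0.0304, -0.0321 and -0.00678, below the preset 0.01. The other called lists had 0.0515 to 0.976. Fry, which asks whether a list's genes move one way on balance, gave 9 lists at an unadjusted p under 0.05 and 0 after adjustment. Old symbols were matched through synonyms of 1 gene alone. In the histone list this left 12 genes.

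Genes and junctions were named by a rule fixed at the same time. Across lines it took the 12 genes that rose and the 12 that fell most, with a mean of at least 1 CPM over the 12 libraries and the same sign in every line, and within a line 6 and 6. A gene named within a line can therefore lie far below 1 CPM there. It took 10 and 10 junctions across lines and 4 and 4 within a line, the 8 genes with the smallest p for differences between lines, the 3 genes of the published study, and from each list up to 4 members by p, of which those that passed are named here. Limiting the junctions named within a line to those called across lines, and the minimum of 20 acceptor reads in the counts by size, were chosen after seeing the data. That minimum was not applied to the named junctions. Genes that tell sex were not reported.

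The steps were tested on simulated counts with 200 changed genes. Across lines, 26.9%, 74.6% and 98.5% of genes changed 1.5, 2 and 4-fold were recovered, with 2 false calls among 20970 unchanged genes. In JVM3 the shares were 46.3%, 61.2% and 89.4% with 6 false calls. The test of differences recovered 58% of 100 genes changed 2-fold in HG3 alone, with 2 false calls. For JVM3 and for the differences, counts were simulated with the spread of technical replicates alone, unlike those across lines. Their false calls therefore leave out differences between cultures. The junction test recovered 39.7% of 199 junctions raised by 20 points, with 0 false calls among 35305. Of 30 unchanged lists 0 were called. Those lists held random genes simulated independently of each other, while the estimated correlation of the real cell cycle list was 0.976. The simulation therefore does not measure false calls among lists of correlated genes.

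Alternatives were another scaling (RLE), DESeq2 1.42.0, no filter on low counts, 12 libraries unsummed, the replicate number as a block, a fold threshold of 1.2, other read and change minimums, limma on log ratios, grouping by donor, thinning, and leaving out each line or library. The prior degrees of freedom of the edgeR fits were read out after the results were seen. Base composition of donors was read from annotated transcripts as an alternative added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.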

Results

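RNA was measured in JVM3, HG3 and MEC1, 3 human cell lines labelled as chronic lymphocytic leukaemia, a cancer of mature B cells. Each line was sequenced with wild-type U1 and with the U1 g.3A>C mutation. U1 is the small nuclear RNA whose 5' end pairs with the start of an intron, the 5' splice site. The 6 groups held 2 technical replicates each, 12 libraries in all, with 29880079 to 39716818 counts assigned to genes per library. A table of splice junctions held 1 column per line and U1 status, with 15537369 to 17917160 junction reads per column. The series set mutant cells against wild-type cells of the same line, which asks what the U1 mutation changes in splicing and in RNA levels. The line was therefore the unit of replication across lines, with n = 3. Values within a line rest on technical replicates only.

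RNU1-1 RNA, a U1 transcript, was higher in the mutant libraries of HG3 and MEC1. In HG3 it stood at 206 ± 60.2 CPM (counts scaled to library size) in mutant and 29.1 ± 0.339 in wild-type libraries (SD, n = 2), a ratio of 7.09 that ran from 5.57 to 8.62 over pairings of replicates. In MEC1 it stood at 24.8 ± 0.846 against 12.9 ± 0.324 (SD, n = 2), a ratio of 1.93. In JVM3 the values were 54.2 ± 0.173 and 40.3 ± 0.373 (SD, n = 2), a ratio of 1.35. Within lines, RNU1-1 passed edgeR's test in HG3 (log2 fold change 2.83, adjusted p = 4.02e-05) and MEC1 (0.89, adjusted p = 0.0431), and not in JVM3 (0.45, adjusted p = 0.194). Across the lines it did not pass, with a log2 fold change of 1.37 (SE 0.73, 3 lines, adjusted p = 0.157 by edgeR), and its response differed between the lines (adjusted p = 0.002 by edgeR). The other U1 genes of the table, summed, had ratios of 0.766 in JVM3, 0.71 in HG3 and 0.87 in MEC1. With RNU1-1 included, the summed U1 counts had ratios of 1.05 in JVM3, 3.69 in HG3 and 1.31 in MEC1. The 21 U1 genes listed are near-identical copies, so the split of reads between them is uncertain, and these counts cannot tell mutant from wild-type U1 sequence. Reads that did not align uniquely are not among these counts, so the sum is not all U1 RNA.

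**Figure D1:**
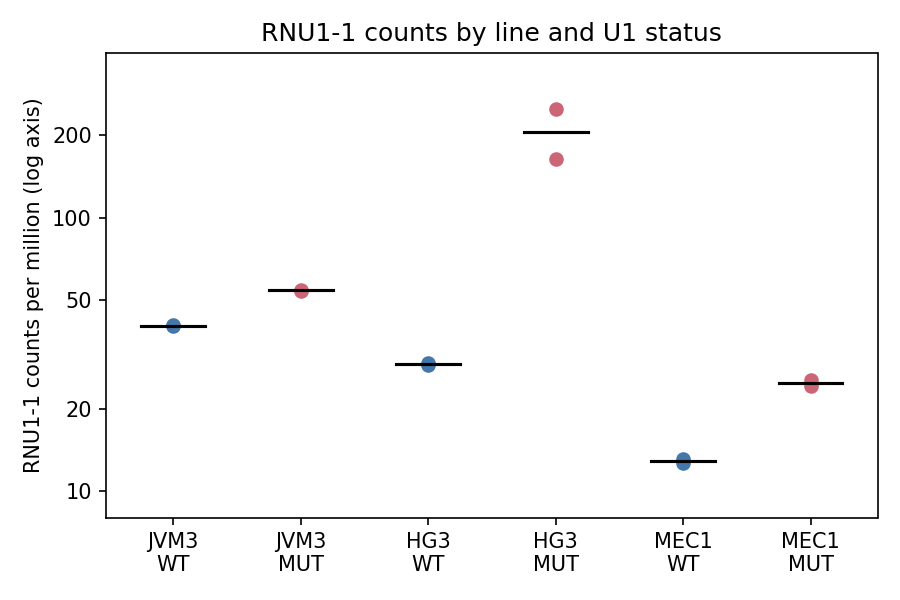
RNU1-1 CPM (log axis) in each line with wild-type (WT, blue) and mutant (MUT, red) U1. Points are the 2 technical replicates and bars their mean, which is higher in mutant than in wild-type libraries by 1.35 times in JVM3, 7.09 times in HG3 and 1.93 times in MEC1.

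Splice site choice shifted in all 3 lines. In PTCD2, which encodes a mitochondrial protein of RNA processing, a junction on chromosome 5 (hg19, 71655354 to 71655431) rose from 3.5% ± 6.1 to 84.3% ± 5.5 of the reads of its acceptor (SD, n = 3 lines). In MYSM1, which encodes a histone H2A deubiquitinase, a junction on chromosome 1 (59160879 to 59165295) rose from 3.3% ± 0.8 to 76.6% ± 9.9 (SD, n = 3 lines). SPPL2A, which encodes an intramembrane protease, shifted from 23.6% ± 6 to 92% ± 2.7 (chromosome 15, 51017520 to 51018270), and CREM, a cAMP-responsive transcription factor gene, from 4% ± 5.1 to 72.2% ± 6.3 (chromosome 10, 35416495 to 35437296). ICE1 shifted from 1.5% ± 0.1 to 61.8% ± 5.9 (chromosome 5, 5475000 to 5476086; each SD over 3 lines). Their adjusted p by edgeR's diffSpliceDGE was 0.00192 for PTCD2, 2.94e-08 for MYSM1, 3.55e-07 for SPPL2A, 1.09e-05 for CREM and 1.8e-09 for ICE1.

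The other junctions with the largest gains lay in RNF34 (76.7 points ± 15.2, SD over 3 lines), KIZ (63.1 ± 24.1), FLVCR1, which encodes a membrane transporter (59.5 ± 10.8), and RABGEF1 (58 ± 11.7), and at a place with no gene matched on chromosome 3 (114693263 to 114863660, 68.7 ± 25.3). The largest losses were the competing junctions of PTCD2, RNF34, MYSM1, SPPL2A, KIZ, CREM and ICE1. They also took in a place with no gene named on chromosome X (3736744 to 3740415, -63.9 points), ABCD3, which encodes a peroxisomal transporter (-58 ± 12.8), and CD44 (-58.1 ± 11.2). PTCD2 and RABGEF1 rested on 84 and 104 acceptor reads over all columns, and SPPL2A and CREM on 1436 and 1317.

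The 3 genes named by the published study each had a junction that passed. These genes were chosen on these or related samples, so they are not independent evidence. In CD44, a hyaluronan receptor gene with alternatively spliced variable exons, the annotated junction from 35211612 to 35236399 on chromosome 11 fell from 86.5% ± 1.3 to 28.3% ± 12.1 of acceptor reads (SD, n = 3 lines, adjusted p = 1.09e-07 by diffSpliceDGE). The annotated junction from 35232996 to the same acceptor rose from 13% ± 1.2 to 69.8% ± 11.4 (adjusted p = 5.47e-10 by diffSpliceDGE). In MSI2, which encodes an RNA-binding protein, an unannotated junction (chromosome 17, 55448352 to 55478740) rose from 1% ± 0.6 to 34.6% ± 7.1 (SD, n = 3 lines, adjusted p = 1.61e-09 by diffSpliceDGE). In POLD1, the catalytic subunit gene of DNA polymerase delta, an unannotated junction (chromosome 19, 50913281 to 50916683) rose from 2% ± 1.2 to 19.4% ± 4.9 (SD, n = 3 lines, adjusted p = 0.0173 by diffSpliceDGE).

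Over 35857 junctions tested at 16167 acceptors, 717 were used more and 281 less in mutant columns, by at least 5 points on average and in the same direction in every line. Of the junctions used more that could be matched to a gene, 45.6% were not annotated, against 10.9% of those used less and 21.7% of the other tested junctions. The odds ratio of used more against the others was 3.05 (95% interval 2.61 to 3.56, two-sided Fisher's exact test, p = 2.98e-43). Among the 717, 457 had under 5% use in the wild-type columns. Without HG3 or without MEC1 the 998 calls became 536 (411 used more, 125 less) and 569 (423 and 146). Percent use is a share of acceptor reads, so a gain at a junction is a loss among its competitors. In POLD1 the gain of 17.4 points was called, while the change of -17 points at a competing junction was not. The split into 717 and 281 thus depends on which junctions pass, and is no measure of net gain. Limma on log ratios called 291, with a more even split of 157 used more and 134 less. In that limma test the junctions of RNF34 (adjusted p = 0.079), RABGEF1 (0.0599), ABCD3 (0.0614), the one CREM used more (0.0647) and the places on chromosomes 3 (0.17) and X (0.0599) did not pass. Without HG3, RABGEF1 (adjusted p = 0.271), ABCD3 (0.108) and the losing junctions of PTCD2 (0.0615) and KIZ (0.247) did not pass, nor did RABGEF1 without JVM3 (0.102) or the losing junction of KIZ without MEC1 (0.117), all by diffSpliceDGE. With too few reads left, some could not be tested, namely both junctions of PTCD2 without MEC1, the place on chromosome 3 without JVM3 or HG3, and that on chromosome X without HG3. At a minimum of 50 reads PTCD2, RABGEF1 and both places were not tested either.

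**Figure D2:**
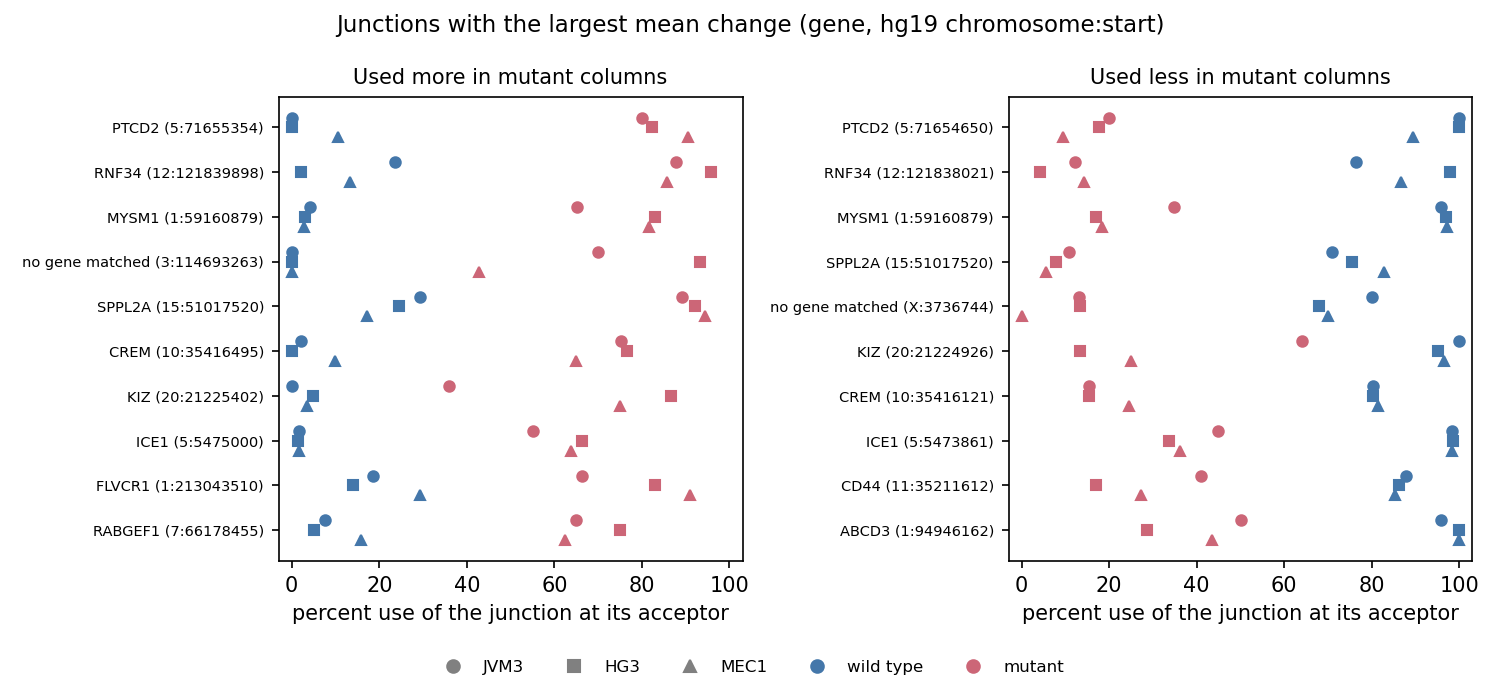
Percent use of each junction among reads of its acceptor (x axis) for the 10 junctions used more and the 10 used less with the largest mean change, labelled by gene and hg19 chromosome and start. Each point is 1 column, with shape for the line and colour for U1 status, and mutant and wild-type points stand apart in every line, as for PTCD2 at 84.3% against 3.5% on average.

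Some junctions were read in mutant columns alone. Of these, 163 had at least 3 reads in the mutant column of every line and none in any wild-type column, while the mirror count was 25. Unannotated junctions of SON (162 reads, chromosome 21, 34932081 to 34933382), which encodes a splicing cofactor, PAN3 (150 reads, chromosome 13, 28750696 to 28751104), a deadenylase subunit gene, and MED14 (143 reads, chromosome X, 40585847 to 40585998), a Mediator subunit gene, were among the deepest. RPL11 (1007 reads) and ELF1 (380 reads) were deeper still. These 2 belong to 587 junctions with at least 100 reads in 1 column and none in another, of which 0.852% were at 0 in exactly the columns of 1 U1 status. RPL11 and ELF1 are the 2 at 0 in exactly the wild-type columns, against 3 at 0 in exactly the mutant columns. At that depth no excess of junctions read in mutant columns alone was seen. The junctions of CREM (192 reads in mutant and 0 in wild-type HG3) and RPRD1B (109 in mutant MEC1 and 0 in wild-type JVM3) are among the 587 too. Of the 163, 147 were matched to a gene and 131 of those were not annotated, with a median of 24 reads over the 3 mutant columns. With all columns thinned to the smallest total, the counts were 148 and 31. At a minimum of 1 read per line they were 914 and 406, and at 5 reads 84 and 12. Without JVM3, HG3 or MEC1, where fewer columns have to meet the rule, they were 595, 600 and 537, with 226, 153 and 189 for the mirror. A count of 0 in 1 column allows up to 3 reads, and no p-value was computed across junctions.

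RNA of the cytoplasmic threonyl-tRNA synthetase fell in each line. TARS1 went from 350 ± 77.7 to 123 ± 29.6 CPM (SD, n = 3 lines), a log2 fold change of -1.53 (SE 0.04, adjusted p = 0.000343 by edgeR). EIF2AK1, which encodes the haem-regulated kinase of eIF2 alpha, fell by 1.28 on the log2 scale, from 134 ± 60.9 to 55 ± 22.4 (adjusted p = 0.00442 by edgeR). PPIL3, a cyclophilin-like isomerase gene, fell by 1.27, from 25.9 ± 1.65 to 10.9 ± 1.4 (adjusted p = 0.00225 by edgeR). NUP37, a nuclear pore gene, fell by 1.21, from 41.3 ± 5.4 to 18.6 ± 6.33 (adjusted p = 0.0121 by edgeR). MEFV, which encodes the innate immune sensor pyrin, rose by 4.88 on the log2 scale (SE 0.9), from 0.0609 ± 0.03 to 1.99 ± 1.35 CPM (adjusted p = 0.00316 by edgeR).

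Other genes that rose were TMEM151B (log2 fold change 5.26, SE 0.76), PAPPA2, a protease gene of insulin-like growth factor binding proteins (3.73, SE 0.27), C6orf52 (3.23, SE 0.21), CSPG5, a proteoglycan gene (2.96, SE 0.8), and ZPLD1 (3.46, SE 0.8). ZPLD1 rested mainly on JVM3, with 476 mutant against 34 wild-type counts. It had 2 against 1 in HG3 and 7 against 1 in MEC1. ZNF418 (2.88, SE 0.76), AVIL, an actin-binding protein gene (2.43, SE 0.63), and FAP, a serine protease gene (2.28, SE 0.5), rose too. DDX59-AS1 (3.86, SE 0.84), TRIM7-AS1 (3.15, SE 0.09) and COP1-DT (2.5, SE 0.29) rose as well. DDX59-AS1 varied between lines, at 5.78 in JVM3, 4.63 in HG3 and 2.88 in MEC1. For these genes reads of overlapping or neighbouring genes may be mixed in, since the strand setting of the counting is not given in the sources used here. The 12 genes that rose most had wild-type means of 0.0609 to 0.94 CPM. Other genes that fell were RAB3B, a GTPase gene of exocytosis (-1.72), OTOGL (-1.61), KCND2, a potassium channel gene (-1.52), KLK1 (-1.43), SOWAHD (-1.37), ADAM23 (-1.32), PYGL, a glycogen phosphorylase gene (-1.25), and PDZD2 (-1.2). Some had few counts in a line. ADAM23 had 3 in mutant against 7 in wild-type HG3 and 3 against 11 in JVM3. PYGL had 2 against 6 in HG3, and RAB3B 1 against 3 in JVM3. By edgeR these did not pass in those lines (adjusted p = 0.344, 0.065, 0.274 and 0.475). OTOGL (0.265) and PDZD2 (0.179) did not pass in JVM3 either.

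In all, 389 genes rose and 395 fell among 21270 tested, and 764 of these 784 had the same sign in every line. By 2-fold or more, 210 rose and 42 fell. The genes named by the study did not pass as genes: CD44 had a log2 fold change of 0.28 (adjusted p = 0.172 by edgeR), POLD1 of -0.79 (adjusted p = 0.0792) and MSI2 of -0.14 (adjusted p = 0.447). Adjusted over the list alone, 1 of these 3 rose and 1 fell, which is not independent evidence. POLD1 passed with DESeq2 (adjusted p = 0.00236), and with edgeR without HG3 (0.0205, with a log2 fold change of -0.51) or without mutant replicate 2 of HG3 (0.0344). With the 12 libraries unsummed, which counts technical replicates as independent, POLD1 (0.00194) and CD44 (0.00338) passed by edgeR. POLD1 also passed by edgeR with no filter on low counts (1.39e-11), a fit in which 91.6% of genes had infinite prior degrees of freedom, so that p rests little on a gene's own spread. DESeq2 called 1326 genes, and without JVM3 edgeR called 460.

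Of the 24 named genes, 12 lost the call when a line was left out (edgeR's adjusted p in parentheses). Without JVM3 these were ZPLD1 (0.451, with a log2 fold change of 1.92 in place of 3.46), CSPG5 (0.0664), KCND2 (0.0828) and ADAM23 (0.0539). Without HG3 they were ZNF418 (0.134) and KLK1 (0.0525). Without MEC1 they were ZNF418 (0.18), AVIL (0.144), RAB3B (0.0639), OTOGL (0.0583), ADAM23 (0.356), PYGL (0.271), NUP37 (0.0505) and PDZD2 (0.114). Among single libraries, AVIL lost it without wild-type replicate 1 of HG3 (0.0611), ADAM23 without mutant replicate 2 of JVM3 (0.0577) and KLK1 without mutant replicate 1 of MEC1 (0.0759). Against a fold threshold of 1.2, AVIL (0.0625), ADAM23 (0.0663), PDZD2 (0.0677), ZNF418 and PYGL (0.0703 each) and KLK1 (0.0707) lost it.

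**Figure D3:**
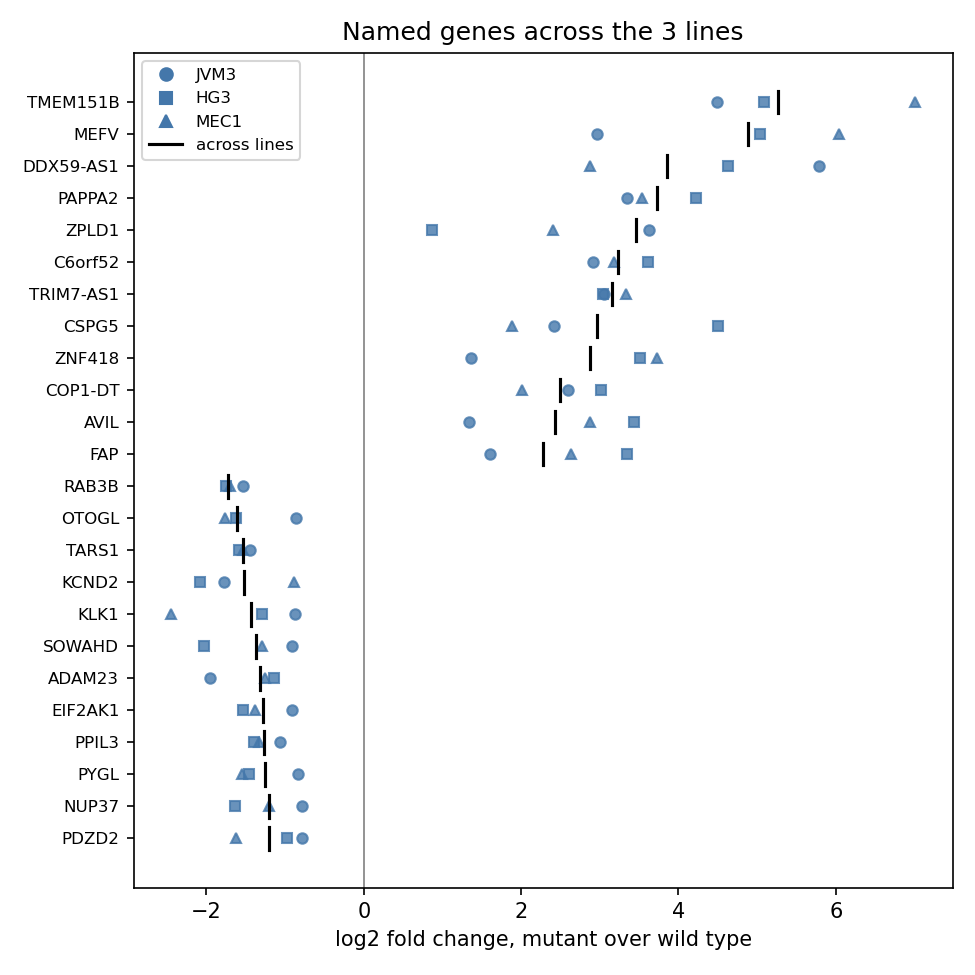
Log2 fold change, mutant over wild type (x axis), of the 12 genes that rose and the 12 that fell most across the lines. Symbols are the lines and black bars the estimate across lines, and TARS1 lies within -1.45 to -1.59 in every line.

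Of 27 genes of the integrated stress response, which raise amino acid synthesis and tRNA charging, 5 fell and 22 did not pass, and adjusted over the list alone 7 fell. PSAT1 (-0.61, SE 0.04), PCK2 (-0.62, SE 0.11), AARS1 (-0.51, SE 0.03) and ASNS (-0.51, SE 0.06) were the first 4 by p (log2 fold changes, n = 3 lines). The list passed limma's camera test (down, adjusted p = 0.00347), but not with an estimated correlation (adjusted p = 0.923). No list passed that version, which has few degrees of freedom, so failing it does not set a list apart. Of 17 plasma cell genes 2 fell (7 adjusted over the list alone), JCHAIN, the joining chain of secreted antibody (-0.75, SE 0.07), and TNFRSF17 (-0.41, SE 0.08). Of 30 B cell receptor signalling genes 2 fell (5 adjusted over the list alone), RASGRP3 (-0.64, SE 0.05) and the kinase gene SYK (-0.71, SE 0.17). Of 26 B cell identity genes 1 fell (4 adjusted over the list alone), CD37 (-0.58, SE 0.15). Camera's adjusted p for these lists was 0.00505, 0.0138 and 0.0209, and 0.923 each with an estimated correlation.

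The histone and cell cycle lists had their lowest medians in HG3. Of 12 replication-dependent histone genes 2 fell (12 adjusted over the list alone), H2BC11 (-0.56, SE 0.09) and H2AC20 (-0.53, SE 0.15), and the median log2 fold change was -0.30 in JVM3, -1.13 in HG3 and -0.41 in MEC1. Of 40 cell cycle genes 1 fell, MCM6 (-0.46, SE 0.14), and adjusted over the list alone 0 did, with 8 at an unadjusted p under 0.05 by edgeR and 6 called by DESeq2. Their median was -0.42 in JVM3, -1 in HG3 and 0.12 in MEC1. Camera's adjusted p was 3.34e-05 for histones and 1.43e-05 for the cell cycle, with 0.923 and 0.928 as the adjusted p with an estimated correlation. Without HG3 the cell cycle list no longer passed (adjusted p = 0.0591), nor did B cell receptor signalling (adjusted p = 0.0925).

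Of 37 type I interferon genes 1 fell (1 adjusted over the list alone), HERC5 (-1.02, SE 0.26). The median was 0.08 in JVM3, -0.47 in HG3 and -0.58 in MEC1 (camera down, adjusted p = 3.34e-05, and adjusted p = 0.928 with an estimated correlation). Of 15 mitochondrial genome transcripts 2 fell (10 adjusted over the list alone), MT-CO3 (-0.55, SE 0.09) and MT-ND3 (-0.46, SE 0.09). Camera called this list down (adjusted p = 0.000711), but not with an estimated correlation (adjusted p = 0.923). The share of reads outside annotated features, which can move with RNA quality, was 18.4% in mutant and 21.6% in wild-type JVM3 libraries, 24.3% and 22.3% in HG3, and 20% and 18.3% in MEC1. Of 29 NF-kB target genes 3 rose (6 adjusted over the list alone), TNFAIP2 (0.6, SE 0.11), the cytokine subunit gene EBI3 (0.45, SE 0.08) and the costimulatory receptor gene CD80 (0.57, SE 0.2). Of 25 p53 targets 1 rose, TP53I3 (0.55, SE 0.12), and adjusted over the list alone 3 rose and 1 fell. Of 40 nuclear oxidative phosphorylation genes 0 passed by edgeR in either count, with 10 at an unadjusted p under 0.05 and 3 called by DESeq2. Camera called these 3 lists up (adjusted p = 0.00347, 0.000711 and 0.00347), with an adjusted p of 0.923 each with an estimated correlation. The NF-kB and B cell identity lists did not pass without MEC1 (adjusted p = 0.0543 and 0.0635), nor oxidative phosphorylation without JVM3 (adjusted p = 0.158).

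Camera did not call the other 24 lists, and 11 of them held a gene that passed (camera adjusted p 0.267 to 0.976). Of 22 targets of nonsense-mediated decay 4 rose, GADD45A (0.5), GADD45B (0.5), SNHG1 (0.39) and BAG1 (0.36), and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.267). Of 29 MYC targets 3 fell, WDR43 (-0.76), HK2 (-0.61) and WDR12 (-0.48), with 1 up and 6 down adjusted over the list alone. HK2 and PDK1 (-0.6) fell among 31 glycolysis and hypoxia genes (2 down adjusted over the list alone). Of 28 hnRNP genes HNRNPA3 fell (-0.48) and HNRNPH3 rose (0.45), with 1 up and 3 down adjusted over the list alone. Of 25 U2 and tri-snRNP genes USP39 fell (-0.52; 1 up and 2 down adjusted over the list alone), and of 20 cleavage and polyadenylation factors RBBP6 rose (0.54; 2 up adjusted over the list alone). Of 11 U1 and variant U1 genes RNVU1-14 fell (-0.6), with 2 up and 1 down adjusted over the list alone. BMF rose among 26 apoptosis regulators (0.39), with 2 up and 2 down adjusted over the list alone. EDEM1 fell among 20 chaperones of the endoplasmic reticulum (-0.45), with 2 down adjusted over the list alone. RPL12 fell among 69 ribosomal protein genes (-0.57), with 0 by edgeR adjusted over the list alone, 5 at an unadjusted p under 0.05 and 2 by DESeq2. CDH1, an adhesion gene, fell among 12 fibroblast and epithelial markers (-1.16), with 1 down adjusted over the list alone.

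In the remaining 13 lists no gene passed by edgeR, over all genes or adjusted over the list alone. They were decay factors, cholesterol synthesis, the minor spliceosome, structured small RNAs, the U1 snRNP and Sm core, SR proteins, heat shock proteins, CLL drivers, MHC class II, telomere maintenance, and markers of T cells, myeloid cells and erythroid cells. Of their 226 tested genes, 44 had an unadjusted p under 0.05 and DESeq2 called 8. Camera's adjusted p ran from 0.163 to 0.869. The median, the mean and camera's direction differed in sign for heat shock proteins, telomere maintenance, myeloid markers, apoptosis regulators, ribosomal proteins and U1 genes.

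Within JVM3, 2214 genes rose and 2553 fell by edgeR's test against the spread of technical replicates, 210 and 173 of them by 2-fold. ZPLD1 was 12.3-fold higher (95% counting interval 8.66 to 17.9), TMEM151B 22.7-fold (11.3 to 53.3), PAPPA2 10.2-fold (5.63 to 20.1), TRIM7-AS1 8.42-fold (3.37 to 27.1) and MEFV 8.11-fold (2.91 to 31.3). The 2 wild-type replicates stood at 0.266 and 0.112 CPM for PAPPA2, 0.0998 and 0.0558 for TRIM7-AS1, and 0.0998 and 0.0279 for MEFV. Their folds therefore depend on the library. DDX59-AS1 had a ratio of 57.9 (19.5 to 283). CD5, a surface marker of this leukaemia, had a ratio of 0.181 (0.0616 to 0.445), at 6 counts against 29. In the other lines CD5 stood at 40.4 CPM in mutant and 41.6 in wild-type HG3 (adjusted p = 0.73 by edgeR) and at 0.0887 and 0.108 in MEC1 (adjusted p = 0.794), and its response differed between the lines (adjusted p = 0.000757). Without mutant replicate 2 the log2 fold change of CD5 in JVM3 was -3.79 in place of -2.39. MAN1C1 had a ratio of 0.227 (0.0836 to 0.535), ATP8B4 of 0.175 (0.0325 to 0.62) and SCNN1D of 0.103 (0.0116 to 0.435). CCR6, a chemokine receptor gene, was at least 2.28-fold lower and LHCGR at least 1.9-fold lower against a floor of 3 counts over the group. These folds take the 6 and 5 wild-type counts as exact, so they do not bound the counting error of both groups. Both genes met the rule of 1 CPM on average through other lines. CCR6 stood at 3.11 CPM in mutant and 2.91 in wild-type MEC1, and LHCGR at 5.85 and 3.88 in HG3. Without wild-type replicate 2 the number of genes called in JVM3 was 3146 in place of 4767. Without that library ATP8B4 (adjusted p = 0.192), CCR6 (0.331), LHCGR (1) and MAN1C1 (0.445, with a log2 fold change of -1.04) lost the call by edgeR, and without mutant replicate 2 they did too (0.134, 0.114, 0.176 and 0.0645). Without mutant replicate 1, CCR6 (0.0951) and LHCGR (0.157) lost it. LHCGR lost it with DESeq2 (adjusted p = 0.0609) and with no filter (0.056), and against a fold threshold of 1.2 LHCGR (0.143) and CCR6 (0.0664) did by edgeR.

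Within HG3, 3971 genes rose and 4174 fell by edgeR's test, 935 and 480 of them by 2-fold. TMEM151B was 34.2-fold higher (23.5 to 51.7) and RUNDC3A-AS1, an antisense gene whose reads are uncertain without the strand setting, 36.8-fold (14.1 to 137), with all wild-type counts of RUNDC3A-AS1 in HG3 in replicate 2. ETV3L, HTRA1, MED12L and ACVR2A had no wild-type counts and were at least 3.7, 3.36, 3.02 and 2.69-fold higher. MEG3, a long noncoding RNA, had no mutant counts and was at least 2.65-fold lower, PTPRJ and the DNA repair gene MGMT at least 2.32-fold each, LRRN3 at least 1.65-fold, and RAB36 and CLEC2B at least 1.32-fold each. These 10 genes had 4 to 11 counts in the other group, taken as exact, so the folds do not bound the counting error of both groups. They lay far below 1 CPM in HG3 and met the rule of 1 CPM on average through other lines. ETV3L, for one, stood at 18.1 CPM in mutant and 16.9 in wild-type JVM3. Their folds in HG3 rest on these few counts alone. Without mutant replicate 1, PTPRJ and MGMT (adjusted p = 0.0556 each), LRRN3 (0.118), RAB36 and CLEC2B (0.172 each) lost the call by edgeR. Without mutant replicate 2 the same genes had 0.0575 (PTPRJ and MGMT), 0.121 and 0.175. Without wild-type replicate 1, MEG3 and RAB36 (0.0884 each) and CLEC2B (0.262) lost it, and without wild-type replicate 2 LRRN3 and RAB36 (0.109 each). DESeq2 did not call LRRN3 (adjusted p = 0.0538), RAB36 (0.0909) or CLEC2B (0.0862). By edgeR, RAB36 and CLEC2B did not pass with no filter (0.0891 each), nor these 3 against a fold threshold of 1.2 (0.0534 for LRRN3, 0.1 each for the others).

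Within MEC1, 3826 genes rose and 3950 fell by edgeR's test, 614 and 333 of them by 2-fold. TMEM151B had a ratio of 151 (41.5 to 1250) and MEFV of 76.5 (20.8 to 637), each against 2 wild-type counts. In MEC1 those of TMEM151B were all in replicate 1 and those of MEFV all in replicate 2. NR2F1, LINC02484, GPRC5B and FXYD6 were at least 2.83, 2.52, 2.2 and 1.89-fold higher. LINC02449 was at least 5.29-fold lower, FAM78B at least 2.47-fold, CADPS2 and GPR15LG at least 2.12-fold each, LIPN at least 1.76-fold and ALDH1L1, a folate enzyme gene, at least 1.41-fold. These 10 genes had 4 to 15 counts in the group that was not at 0, taken as exact, so the folds do not bound the counting error of both groups. They lay far below 1 CPM in MEC1 and met the rule of 1 CPM on average through other lines. ALDH1L1, for one, stood at 74.4 CPM in mutant and 93.6 in wild-type JVM3. Their folds in MEC1 rest on these few counts alone. Of these 12 genes, TMEM151B, MEFV and LINC02449 kept the call by edgeR whichever MEC1 library was left out. Without mutant replicate 1, GPRC5B (adjusted p = 0.281), FAM78B (0.0563), CADPS2 (0.082), GPR15LG (0.0996), LIPN (0.12) and ALDH1L1 (0.175) lost it. Without mutant replicate 2 these were NR2F1 and FXYD6 (0.124 each), CADPS2 (0.0515), GPR15LG (0.0672), LIPN (0.0821) and ALDH1L1 (0.128). Without wild-type replicate 1 they were LINC02484 (0.056), GPRC5B (0.0819), FXYD6 (0.109), GPR15LG (1) and LIPN (0.253). Without wild-type replicate 2 they were GPRC5B (0.064), FXYD6 (0.0858), FAM78B (0.0989), CADPS2 and ALDH1L1 (0.281 each). ALDH1L1 was not called by DESeq2 (adjusted p = 0.0716), or by edgeR with no filter (0.0776) or against a fold threshold of 1.2 (0.095).

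The lines shared calls. JVM3 and HG3 shared 1303 genes that rose and 1582 that fell, where independent lists of these sizes would share 413 and 501. For JVM3 and MEC1 the numbers were 1266 and 1323, against 398 and 474, and for HG3 and MEC1 1877 and 2046, against 714 and 775. All 3 lines shared 923 genes that rose and 990 that fell, against 74 and 93. Each line had its own wild-type libraries, and no test was run on these overlaps.

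Junction use within 1 line was counted by size with no test, since each group had 1 column. At least 5 points of gain and loss were seen at 4484 and 4538 junctions in JVM3, 5130 and 5182 in HG3, and 5773 and 5790 in MEC1, among those with 20 reads at the acceptor in both columns. These counts include junctions that differ by counting error alone. Among junctions called across lines, the largest gains in JVM3 included EXOG, an endonuclease gene, which went from 14.9% (95% Wilson interval 7.4 to 27.7) to 86.5% (72 to 94.1) on chromosome 3 (38541655 to 38542846). In HG3 they included RNF34, from 2.2% (0.4 to 11.3) to 95.7% (89.6 to 98.3), and KIZ, from 4.8% (0.8 to 22.7) to 86.7% (70.3 to 94.7). In MEC1 they included RPRD1B, from 2.3% (0.8 to 6.6) to 77.3% (69.7 to 83.4) on chromosome 20 (36665936 to 36668837), while in JVM3 that junction went from 0% (0 to 4.8) to 29.6% (20.2 to 41). PTCD2 was among the 4 largest gains in each line, but no line had 20 reads at its acceptor in both columns. Its use was 80% (37.6 to 96.4), from 4 reads, in mutant JVM3, 82.4% (59 to 93.8) in HG3 and 90.5% (71.1 to 97.3) in MEC1. In wild-type columns it was 0% (0 to 29.9), 0% (0 to 22.8) and 10.5% (2.9 to 31.4).

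Lines also differed in response. Histone gene H1-5 had a log2 fold change of -1.65 in HG3, -0.45 in JVM3 and -0.26 in MEC1, and H4C3 had -1.36, -0.32 and -0.27. RRM2, a ribonucleotide reductase gene, had -1.19 in HG3, -0.56 in JVM3 and 0.16 in MEC1, CENPF, a kinetochore gene, -1.04, -0.54 and 0.15, and CDC20, a mitotic regulator gene, -1.08, -0.21 and 0.36. ALPK2 had 1.45, 0.59 and -0.26, and ASAH1, the acid ceramidase gene, 1.02, -0.19 and -0.17. CTNND1, which encodes p120 catenin, had 1.68 in MEC1, 0.13 in HG3 and -0.1 in JVM3. These 8 had the smallest p of edgeR's test of the differences between lines, which called 6802 of 21270 genes against technical spread. Of the genes called within lines, 1146 passed in opposite directions in different lines. The planned test of the donor's sixth intron base in the files' own genome build was not run, because no genome of that build was used here.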

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

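All 3 tests on JVM3 were chosen after its smaller effect was seen. The totals and RNU1-1 levels had been seen by then, while the test on the general response was set before its own value, with donor bases read in a way chosen after seeing the data. Lines differed in their response to mutant U1 by edgeR's test of the difference itself, with 6802 genes called, and 11 of the 24 genes named across lines were among them. The smallest adjusted p belonged to H1-5 (1.43e-25), ALPK2 (1.62e-24), ASAH1 (1.6e-22), CTNND1 (7.2e-22), RRM2 (1.28e-21), CENPF (1.3e-21), H4C3 (1.91e-21) and CDC20 (2.49e-21). These p-values rest on technical replicates, so a difference between 2 cultures would look the same.

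The mutant effect was smaller in JVM3. The junctions used more gained a median of 11.1 points in JVM3, 16.7 in HG3 and 17.1 in MEC1, and JVM3 had the smallest gain for 458 of 717. JVM3 did not have lower gene totals, with 1.07 times the summed gene counts of the other lines' mean. Its junction columns were the highest (mutant, 17917160 reads) and the lowest (wild type, 15537369 reads) of all. Percent use is a ratio that depth does not scale, so these totals cannot decide whether depth played a part. A further test took 1031 acceptors with a donor that has G at the sixth intron base and a competitor without it, chosen without regard to change. Over them the mean change in JVM3 was 0.632 of that in the other lines (95% bootstrap interval 0.499 to 0.762), as a weaker response in general would give. Acceptors of called junctions were not left out, so this is not independent of the smaller gains above. The interval is over acceptors, with 1 column per group, and does not measure spread between cultures. The RNU1-1 ratio was lower in JVM3, at most 1.36 over pairings of replicates against at least 1.85 in the other lines, but its gain was 13.9 CPM in JVM3 (13.5 to 14.3 over pairings) and 12 in MEC1 (11.1 to 12.8). Summed over the 21 U1 genes, JVM3 had 87.4 CPM in mutant and 83.7 in wild-type libraries, a ratio of 1.05. The summed ratio was 1.31 in MEC1 (40.9 against 31.3 CPM) and 3.69 in HG3 (229 against 62.1 CPM). Ratio and gain thus disagree for RNU1-1 alone, and for the sum both were lowest in JVM3. Whether a lower dose of mutant U1 contributes cannot be told apart from other differences between the lines. The counts leave out reads that did not align uniquely and do not separate mutant from wild-type U1.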

How the results depend on the processing

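The scalings and minimums were set before the data were examined, and the alternatives for donor bases and the acceptor minimum within lines were added after. Of genes changed across lines, DESeq2 called 1326, no filter 2540, the 12 libraries unsummed 6641, and a fold threshold of 1.2 left 198, where the main test called 784. With no filter, prior degrees of freedom were infinite for 91.6% of genes across lines and 96.7% within lines, against 0% in the main tests, so its p-values rest little on a gene's own spread. Of the 784, 783 to 784 kept their sign under each alternative. Leaving out a line or a library gave 460 to 992. The replicate number as a block gave 5084 across lines, POLD1 (adjusted p = 0.0102) and CD44 (0.0191) among them. With that block, genes changed in JVM3 were 5773, genes changed in HG3 8871, genes changed in MEC1 8603, and genes whose mutant effect differs between lines 7992, while RAB36 (0.0547) and CLEC2B (0.0579) in HG3 had an adjusted p over the threshold. Deviations of replicates with the same number in the same line correlated at 0.07 in HG3, 0.06 in JVM3 and 0.23 in MEC1, and those of groups of different lines at 0.05 to 0.22. All were positive, so an effect shared by libraries with the same number is not excluded. Since some pairs lay under 0.1, the numbers were not taken to pair samples, and unsummed libraries count technical replicates as if they were independent. Within lines the fold threshold left 873 genes in JVM3, 3552 in HG3 and 2830 in MEC1, and leaving out a library gave 3146 to 3264 in JVM3, with 1 library alone in its group taken to vary like the others. Limma on log ratios called 291 junctions, 192 of them among the 998, grouping by donor 706, 220 of them among the 998, and leaving out a line 536 to 812. A minimum of 50 reads gave 4629, 5417 and 6098 junctions by size in JVM3, HG3 and MEC1, and 10 points gave 3760, 4900 and 5564. Junctions read in mutant columns alone were 914 (mirror count 406) at 1 read and 84 (mirror count 12) at 5 reads per line, a ratio of 2.25 and 7 against 6.52 at 3 reads, and 537 to 600 without a line, where fewer columns have to meet the rule. With an estimated correlation 0 gene lists passed, and 1 had an unadjusted p under 0.05. Every result recomputed with RLE scaling kept its direction and its side of the threshold, and every such count stayed within 1.5 times. The cause of the other changes was not tested. Not run were the junction tests with 12 libraries, with a replicate block or without single libraries, since the columns are pooled, and the donor base test in the files' own build. Of simulated 1.5-fold changes 26.9% were recovered across lines. Depth leaves folds against a group with no counts as values against a floor, with the other group's count taken as exact.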

Other observations

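The tests on donor bases, on junctions at 0 in some columns and on pseudogenes were chosen after the results were seen, while the splits and the tests on genes that fell were set before their own values, after the changed genes and junctions had been seen. Donors of junctions used more differed from others in their bases. Base 3 of U1 faces the sixth base of the intron, and the mutation from A to C changes its partner from U to G. Where the donor could be read from annotated transcripts, 74.2% of 229 junctions used more had G there, against 24.7% of 89 used less and 22.9% of 9926 others (odds ratio 9.68, 95% interval 7.13 to 13.3, two-sided Fisher's exact test, p = 7.24e-59, adjusted p = 2.6e-57 over 36 positions and bases, the smallest). T there was found in 14.4% against 41.8%. The odds ratios set junctions used more against all others, those used less included. Other positions differed too, with A at the seventh base in 51.1% against 27.5% (odds ratio 2.75, adjusted p = 1.76e-12), G at the fifth in 82.5% against 71.8% (adjusted p = 0.00133) and T at the third in 10% against 5% (adjusted p = 0.00754), all by the same test. Whether these differences go with the sixth base was not tested. The share with G ran from 64.5% to 89.7% under other settings of the junction test. This is consistent with altered pairing of U1 with the donor as a candidate cause, but 229 of 717 could be read, and a donor read from a transcript must lie inside an exon of another form.

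Genes that fell often held a junction used more. Such a junction was found in 29.2% of 216 genes that fell, 16.2% of 111 that rose and 8.1% of those that did not pass. Only genes with a tested junction matched to them were counted, out of 395 that fell and 389 that rose. The odds ratio of fell against rose was 2.12 (95% interval 1.16 to 4.05, two-sided Fisher's exact test, p = 0.0103). Transcripts with a junction used more may therefore be lost. Within 4 strata of junction reads the odds ratio was 2.03 (1.09 to 3.94, exact conditional test, p = 0.0237), which argues against depth as the whole cause. Whether transcripts are lost was not tested.

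Some junctions were deep in 1 column and absent in another. Of 39479 junctions with at least 100 reads in a column, 587 had none in another, in 57 combinations of columns, and 0.852% of them separated mutant from wild type exactly. This is consistent with alignment or filtering that differed between columns. Of 429 of these with a named gene, 25.4% lay in genes with a processed pseudogene named after them, against 12.5% of other deep junctions (odds ratio 2.38, two-sided Fisher's exact test, p = 5.33e-13), so reads shared with pseudogenes may contribute. Of the 587, 9 were called across lines, and for these a change in use stays open too. Neither explanation was excluded, and 198 of the 587 were at 0 in whole lines, where a difference between lines stays open.

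Splitting the 6 summed libraries or columns into 2 groups of 3 can be done in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, called 784 genes, 998 junctions and 11 gene lists, and the highest other split called 0 genes, 0 junctions and 8 lists. Each other split either parts the pair of 1 line alone or swaps the status of 1 line. Either way the mutant effect of other lines enters the spread, so few genes or junctions could pass. These 0 counts therefore do not measure chance. The rule of the same sign in every line, applied to splits that part all 3 lines, lowers the junction counts, which were 1030 and at most 4 without it. That 8 of 35 lists passed in a split that mixes mutant and wild-type cells is a limit on the list calls.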
